A study of Arabidopsis thaliana with 8 samples.

How the data were processed

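Polyadenylated RNA from seedlings of Arabidopsis thaliana (Col-0 background, 10 days old, grown on plates in long days, per the labels) was sequenced in 8 libraries. Wild type (WT) and mom1 had 2 libraries each, and the mutants labelled pial1/2, pial2, mom1pial2 and nrpe1 had 1 each. The deposited files are 6 tables, each comparing 1 mutant library with 1 WT library. WT replicate 1 is in the tables of mom1 replicate 1, pial1/2 and nrpe1, and WT replicate 2 is in the tables of mom1 replicate 2, pial2 and mom1pial2. The submitters' processing notes name TopHat2 2.0.12 with Bowtie for alignment to TAIR10, Cufflinks 2.2.1 for quantification and Cuffdiff for the comparison, with no version given for Bowtie or Cuffdiff. Nothing in the labels states read length, strand or read filters.

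Per the file headers, the authors' expression values are FPKM per gene, scaled within each table to its 2 libraries. The same WT library differed between tables by a factor between 0.981 and 1.01 that was nearly constant across genes, so levels were compared as ratios within a table. The deposited p-value and q-value of each gene come from the authors' Cuffdiff test of the 2 libraries in the table. A check of the q-values showed that they are Benjamini-Hochberg adjusted over the genes with test status OK, to within 4.69e-06. A gene was taken as called when the authors' q-value lay below 0.05. Each table has 34133 entries, of which 21562 to 22230 were tested by the authors. In the mom1 replicate 1 table LHCB1.3 is listed at 0 with a status for excess data, and it was left out of the mom1 fit.

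Entries were matched by locus identifier to the TAIR10.1 annotation, and 33389 of 34133 matched. The annotation has no separate class for transposable element genes. Genes with the biotype pseudogene were taken as the transposon class, which holds 4483 entries and all 8 of the transposon loci written down before the data were examined. Pericentromeric windows, also set beforehand, run from 12 to 18 Mb on chromosome 1, 1 to 7 Mb on chromosome 2, 11 to 17 Mb on chromosome 3, 2 to 6 Mb on chromosome 4 and 9 to 16 Mb on chromosome 5. They hold 82.0% of the transposon class and 11.6% of other entries. The tables merge overlapping genes into shared intervals, and entries that share an interval were not counted. By locus identifier without its transcript suffix, 1141 entries share a locus with another entry.

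Log2 ratios were taken on FPKM plus a pseudocount of 1. For mom1 the 2 within-table ratios were fitted with limma 3.58.1 in R 4.3.3 (intercept only, empirical Bayes, two-sided, Benjamini-Hochberg at 0.05), over 20517 genes with at least 1 FPKM in at least 1 of the 4 libraries. A gene silent in WT meets this minimum only through mom1. In the other tables lists were measured over genes with at least 1 FPKM in either library, with the same limit. Because each ratio pairs libraries of the same number, the fit blocks on the replicate. On simulated data of this size the fit recovered 4% of genes changed 2-fold, 82% of those changed 4-fold and 98% of those changed 8-fold, and 9 of its 149 calls were false. Each size had 50 changed genes, altered by the same amount in both tables. Recovery of real changes that vary between the tables may be lower. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest.

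The lists, fixed before the data were examined, were the mutated genes, RNA-directed DNA methylation, heterochromatin maintenance, DNA demethylation, the SUMO pathway, known silenced loci, heat response, salicylic acid defence, jasmonate and wounding, abscisic acid with cold and drought, morning clock genes, day and evening clock genes, nuclear photosynthesis genes, root markers, seed markers, flower markers and flowering time. The transposon class and the other pericentromeric genes were added from the annotation. Camera tested these lists except the mutated genes. For the mutants with 1 library, a list was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on expression, with no p-value. Tests on 2 libraries compare those libraries and not the genotypes, and these comparisons have no replicate check.

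Overlaps of called genes were set beside the overlap of independent lists, n1 x n2 / N. For tables that share a WT library they were also set beside 200 simulations of unchanged mutants against that library, over genes with at least 1 FPKM in either library of every table, with normal noise of the robust spread between the 2 mom1 ratios and, added after seeing the data, with noise resampled from those differences, which keeps their tails. The simulated lists were the top-ranked genes, as many as the authors had called, with no test applied. The double mutant and nrpe1 were compared with single mutants through differences of log2 ratios.

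Named genes followed a rule set before the data were examined. For mom1 it took the 12 up and 8 down called in both tables with the largest smaller ratio, with at least 1 FPKM in a library of each table. For each other mutant it took the 8 up and 4 down called genes with the largest ratio. It also took up to 10 called up in mom1, pial1/2, pial2 and mom1pial2, up to 5 called up in mom1 and nrpe1, and the 5 highest and 3 lowest called genes of mom1pial2 relative to the higher of its single mutants. The mutated genes and up to 4 members of every other list with the largest mom1 ratio completed it. Other genes are named as chosen after their values were seen.

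Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, ratios centred on their median, a mean-variance trend, no replicate block, all 8 libraries in the fit, leaving out each library, q-values below 0.01, an added 2-fold minimum, windows narrowed by 1 Mb, and calls by 2-fold alone. Summing entries that share a locus and a minimum of 1 FPKM in WT were added after seeing the data. The tables give no read counts, and no counting interval was computed. Where both libraries of a table lay above 0 and under 0.3 FPKM, 80.3% to 89.7% of the ratios were, to within 0.3%, a ratio of small whole numbers times 1 factor per table, the worth of 1 fragment in the mutant library relative to WT. This factor was 0.665 for mom1 replicate 1, 1.06 for mom1 replicate 2 and pial2, 1.02 for pial1/2, 1.13 for mom1pial2 and 0.999 for nrpe1. A depth in fragments was not taken from these steps, since their scale is that of the authors' normalization. The sum of FPKM per library was between 903183 and 1057854.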

Results

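Transcript levels were measured by mRNA sequencing in 10-day-old seedlings of wild type (WT, 2 libraries), mom1 (2 libraries), and the mutants labelled pial1/2, pial2, mom1pial2 and nrpe1 (1 library each). MOM1 is a nuclear protein needed for transcriptional gene silencing. PIAL1 and PIAL2 are SUMO E3 ligase-like proteins that the series title describes as partners of MOM1 in silencing, and NRPE1 is the largest subunit of RNA polymerase V in RNA-directed DNA methylation. The comparisons ask which transcripts each mutant gains or loses against WT, and how far the mutants have gains and losses in common. The tables give FPKM and no counts, so the depth in fragments is not known. By the steps of the low FPKM values, 1 fragment in mom1 replicate 1 was worth 0.665 times as much as in the WT library of its table, so that library was the deeper of the pair, while in the other 5 tables the factor lay between 0.999 and 1.13. Nothing in the labels states that replicates came from separate cultures or plants. The limma p-values therefore measure only the spread between these samples, with spread borrowed across genes. The authors' p- and q-values each compare 2 libraries and measure no spread between replicates.

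The mutated genes were examined first, in every library. MOM1 (AT1G08060, chromosome 1, 2501742 to 2511084) stood at 6.10 FPKM in WT and 1.61 in mom1 in the replicate 1 table, and at 4.90 and 1.15 in the replicate 2 table. In mom1pial2 it was 1.29 FPKM against 4.99 in WT. In the library labelled pial1/2 it was 5.73, in pial2 4.13 and in nrpe1 5.82. NRPE1 (AT2G40030, chromosome 2, 16714494 to 16723583) was 1.16 FPKM in nrpe1 against 4.61 in WT, and lay between 2.45 and 3.54 in the other mutants. PIAL2 (AT5G41580, chromosome 5, 16626337 to 16630783) was 1.96 FPKM in pial2 and 2.13 in mom1pial2, against 5.52 and 5.53 in WT. In the library labelled pial1/2 PIAL2 was 4.79 FPKM against 6.47 in WT, and PIAL1 (AT1G08910, chromosome 1, 2856227 to 2861170) was 11.3 against 11.7. The authors' deposited table called neither gene in that library, with q-values of 0.290 for PIAL2 and 0.99994 for PIAL1. Total FPKM therefore does not check the label of that library, which is referred to as the library labelled pial1/2. In the remaining mutants PIAL1 lay between 7.07 and 11.1 FPKM, and in mom1 and nrpe1 PIAL2 lay between 4.62 and 6.57.

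**Figure D1:**
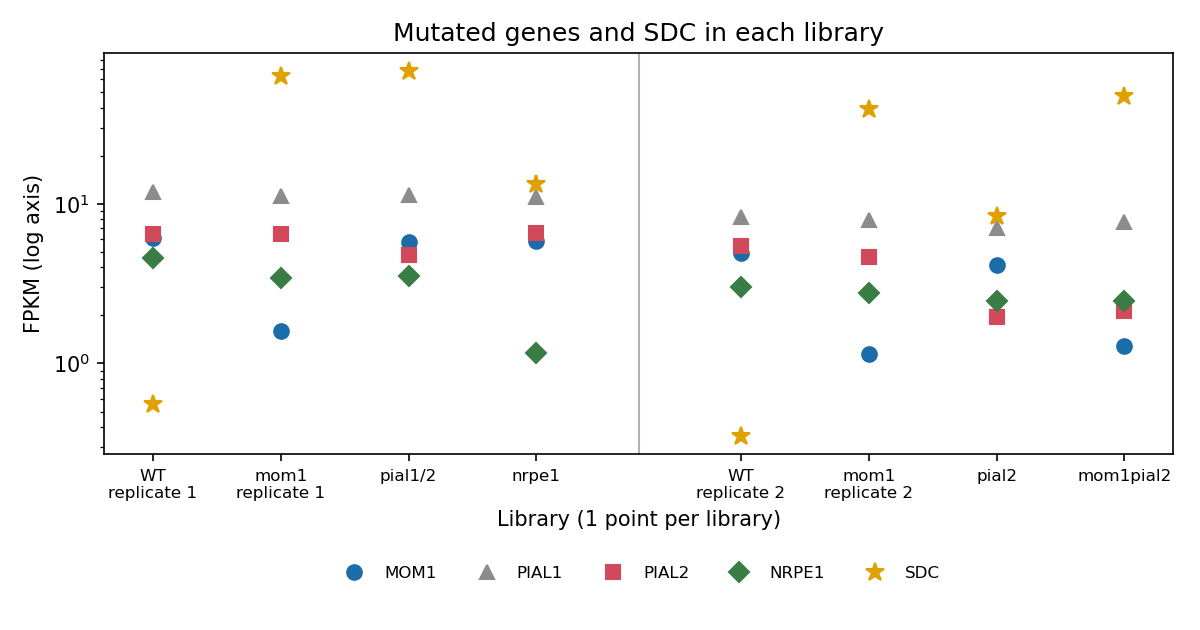
FPKM (log axis) of the 4 mutated genes and of SDC in each of the 8 libraries. MOM1 is low in mom1 and mom1pial2, NRPE1 in nrpe1, and PIAL2 in pial2 and mom1pial2, while PIAL1 and PIAL2 in the library labelled pial1/2 stand at 11.3 and 4.79.

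The 8 libraries fell into 2 sets by their clock genes, and the sets were those of the WT library they are tabulated with. CCA1, a morning transcription factor of the circadian clock, stood at 10.1 FPKM in WT replicate 1 and 148 in WT replicate 2. The median log2 difference of WT replicate 2 minus WT replicate 1 was 2.67 over the 7 morning genes, of which 7 lay above 0. Over the 9 day and evening genes the median was -2.16, and 0 lay above 0. PRR5, an evening repressor, was 31.2 FPKM in WT replicate 1 and 0.315 in WT replicate 2. The median FPKM of the morning genes was between 4.90 and 11.8 in the 4 libraries of the first set, and between 58.9 and 65.4 in the 4 libraries of the second. Of 19196 expressed genes, 2653 (13.8%) differed at least 2-fold between the WT libraries, against 211 within the first mom1 table and 328 within the second. These levels come from separately normalized tables, between which the median gene differed by -0.07. The library labelled pial1/2 and nrpe1 exist only in the first set, and pial2 and mom1pial2 only in the second, so any contrast across them is confounded with the set. The mom1 comparison was made within each.

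**Figure D2:**
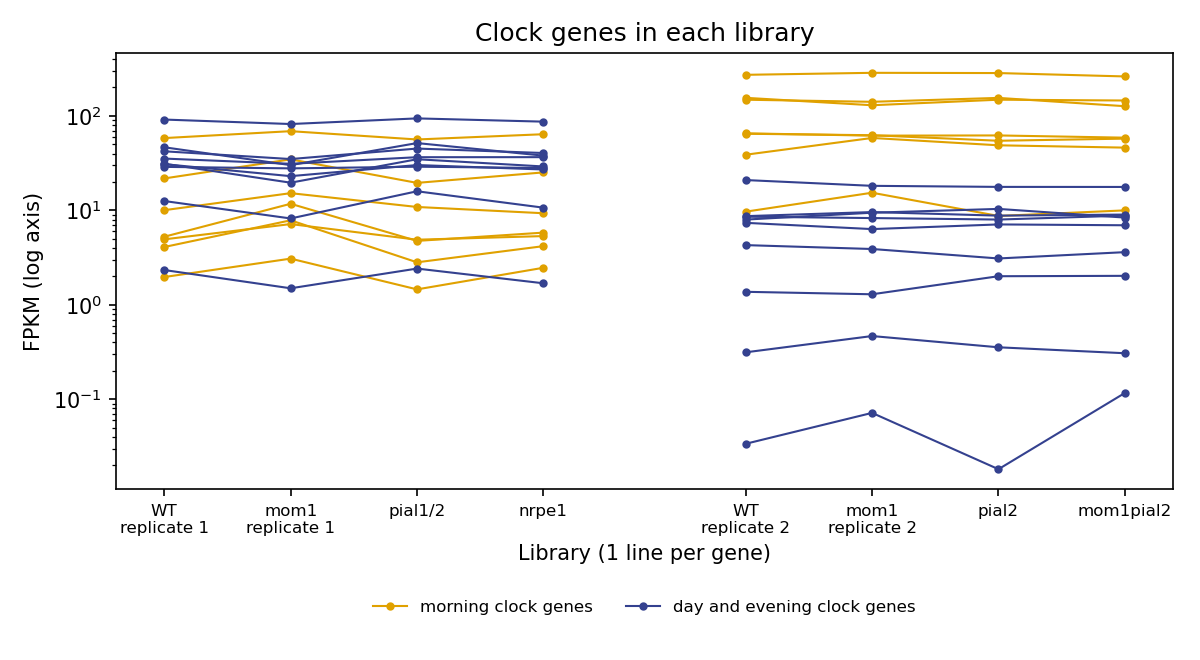
FPKM (log axis) of clock genes in the 8 libraries, grouped by the WT library they share a table with. CCA1 stands at 10.1 in WT replicate 1 and 148 in WT replicate 2, and PRR5 at 31.2 and 0.315.

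By limma, 18 genes rose in mom1, and 17 of them lie in the pericentromeric windows, though not all were silent in WT (AT5G35480 stood at 47.5 FPKM in WT replicate 1, MRU1 at 16.7 and SQN at 12.2). AT3G29639, a short protein-coding gene, rose by a mean log2 ratio of 6.65 ± 0.30 (SD, n = 2 tables), from 1.55 to 219.8 FPKM in replicate 1 and from 2.1 to 358 in replicate 2. The transposon-class gene AT4G04293 rose by 6.55 ± 0.20, from 3.07 to 419.5 FPKM in replicate 1. SDC, an F-box gene that DNA methylation keeps silent in seedlings, rose by 5.13 ± 0.34, from 0.555 to 63.2 FPKM in replicate 1 and from 0.350 to 39.0 in replicate 2.

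The risen genes lay on all 5 chromosomes and several were neighbours. On chromosome 2, AT2G11780 (4729678 to 4732966, transposon class) rose by 6.31 ± 0.03, with an adjusted limma p of 0.0199. Next to it AT2G11778 (4728072 to 4728239, protein-coding) was at 1286 FPKM against 1.87 in replicate 1 and 3126 against 16.5 in replicate 2. Its log2 ratio of 8.14 ± 0.94 was the highest of the named genes but missed the limma threshold (adjusted p = 0.0513). Also on chromosome 2, AT2G15810 (6882821 to 6886775, transposon class) rose by 6.11 ± 0.32. The interval 6877774 to 6882741 beside it holds AT2G15800 (transposon class) and SQN, a cyclophilin gene, and reads may be split between these overlapping entries. SQN, chosen after its values were seen, rose by 3.66 ± 0.28. AT2G15800 stood at 5.93 ± 0.65 and did not pass limma (adjusted p = 0.0513). On chromosome 3, AT3G42353 (14497056 to 14497541) rose by 6.03 ± 0.42. AT3G42719 (14803536 to 14804201), listed at 0 in WT replicate 1, was at 20.3 FPKM in mom1 replicate 1 and at 20.7 in replicate 2, and rose in limma. On chromosome 1, AT1G36680 (13871080 to 13872202) rose by 4.15 ± 0.26. On chromosome 4, AT4G06615 (3283784 to 3284823) was listed at 0 in WT replicate 1 and rose to 14.5 FPKM, and 49.5% of its 50-base windows occur elsewhere in the genome. On chromosome 5, AT5G35480 (13689204 to 13689558) and its neighbour MRU1 (13689817 to 13690548) rose by 3.82 ± 0.13 and 3.36 ± 0.00. AT2G04460, a transposon-class gene on chromosome 2, was higher by 4.76 ± 0.63 but did not pass limma (adjusted p = 0.0661).

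The authors' deposited tables called 222 genes up and 249 down in mom1 replicate 1, and 212 up and 295 down in replicate 2. The same direction was called in both of the authors' deposited tables for 110 genes up and 53 down, and opposite directions for 7. The overlap of independent lists would be 1.84 up and 3.29 down. Of the 110 genes up in both of the authors' deposited tables, 67 (60.9%) were of the transposon class, which made up 1.09% of the genes tested in both. Which of these loci were tested depends on the mutant. Their share of tested genes ranged from 0.779% in pial2 to 1.46% in mom1 replicate 1, while the class holds 4483 of all 34133 entries. The contrast with 1.09% therefore depends in part on the change itself. Another 21 were other genes in the pericentromeric windows and 22 were other genes on the chromosome arms. Among the 53 genes called down in both of the authors' deposited tables, 4 were of the transposon class and 46 were other genes on the arms. Both limma and the authors' deposited tables called 16 of the 18 genes. The others were AT3G30843 (transposon class, 4.79 on the log2 scale) and AT3G29633, an annotated gene at chromosome 3, 11452942 to 11453037, that was listed at 0 in both WT libraries. The median share of 50-base windows that occur elsewhere in the genome was 11.9% over the 67 transposon-class genes, of which 32 lay under 10% and 6 over 50%, so reads of these genes may be shared with other copies. It was 0% over the other 43 genes, of which 2 exceeded 50%.

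**Figure D3:**
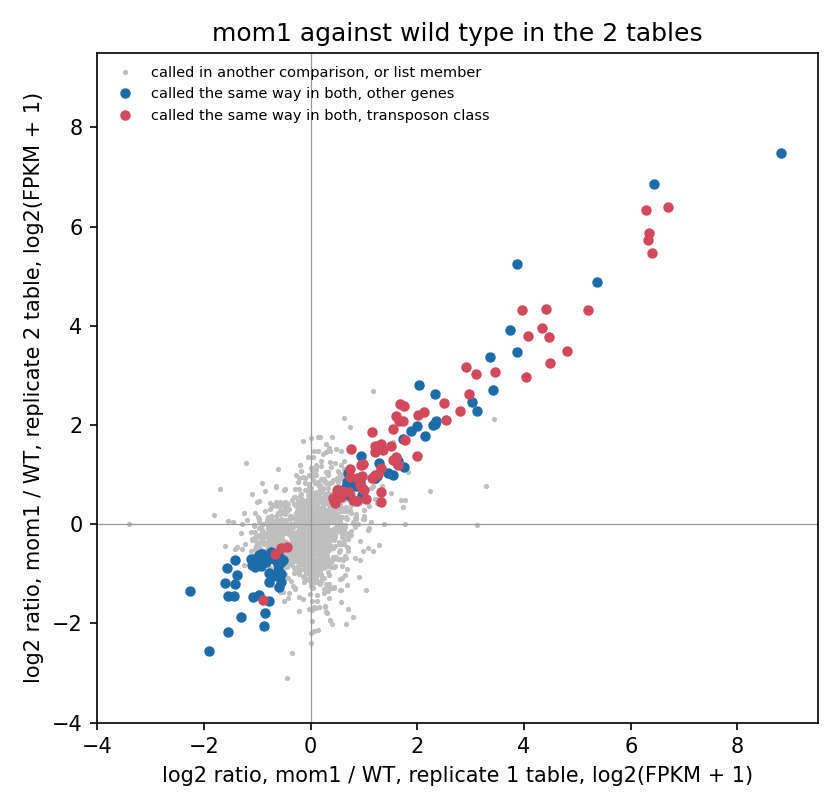
Log2 ratio of mom1 to WT in the replicate 1 table (x axis) and in the replicate 2 table (y axis), on FPKM + 1. Coloured points are the 110 genes called up and 53 called down in both of the authors' deposited tables, and grey points are other called or listed genes (LHCB1.3, listed at 0 in mom1 replicate 1, falls outside the axes).

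**Figure D4:**
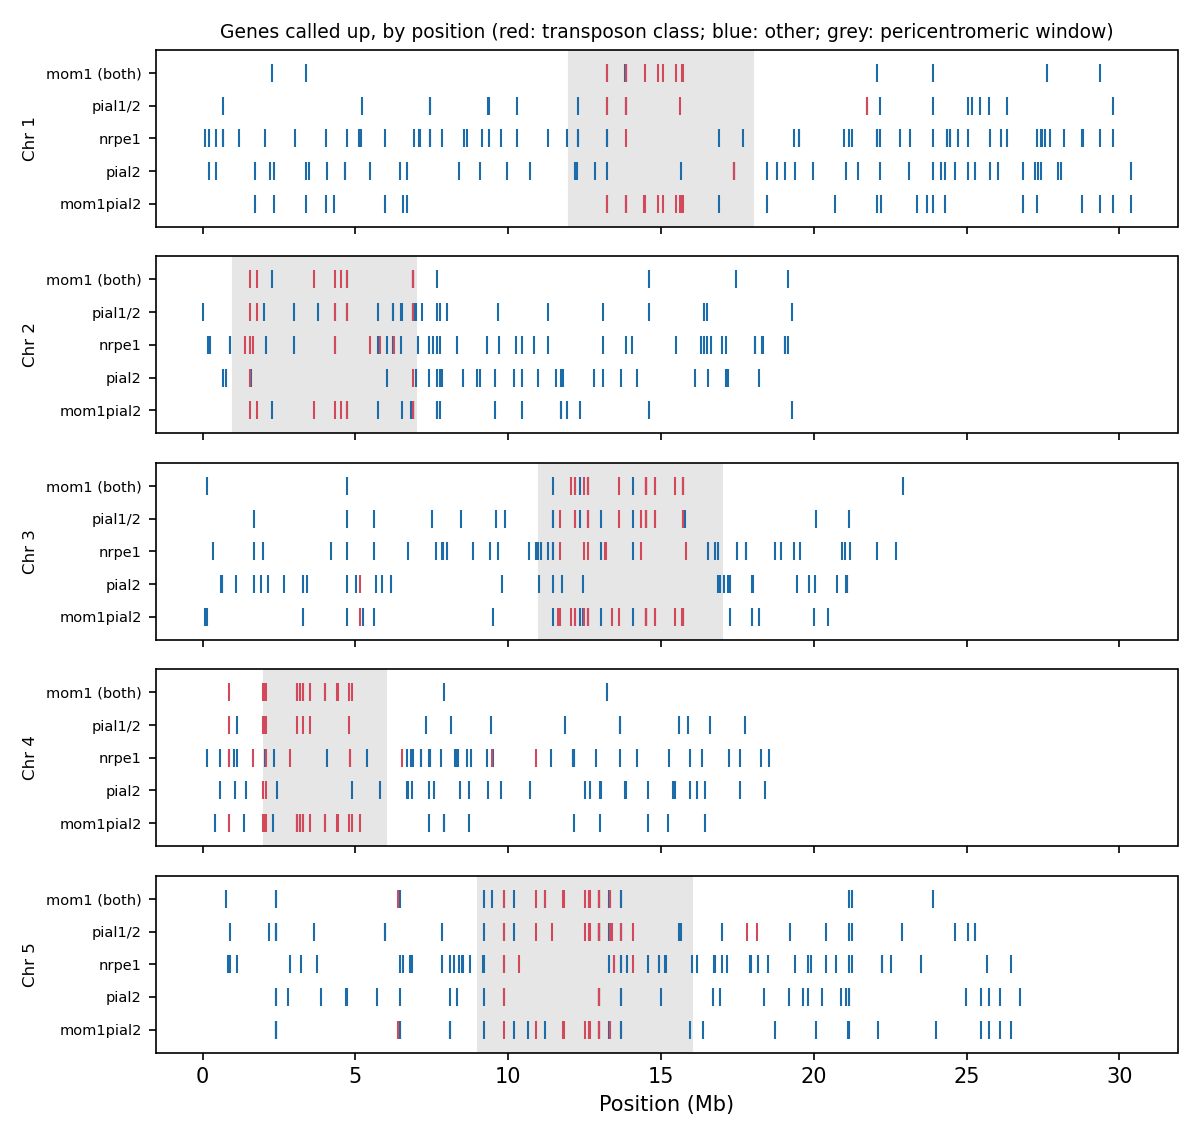
Position in Mb along the 5 chromosomes of genes called up in the authors' deposited tables, with the pericentromeric windows shaded. Each mutant has its own row, and the mom1 row holds the genes called up in both mom1 tables. Colour marks the transposon class, and genes called down are not drawn. Of the 110 genes called up in both mom1 tables, 85 lie in the windows.

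Lower transcripts in mom1 included TCH4 (AT5G57560, chromosome 5, 23307130 to 23308282), a touch-induced cell wall enzyme, which was at 231 FPKM against 867 in replicate 1 and 11.5 against 72.3 in replicate 2. EXO and PHI-1, related growth-associated genes, had mean log2 ratios of -1.86 ± 0.44 and -1.80 ± 0.64. CSD2 (AT2G28190), the plastid copper/zinc superoxide dismutase, was at -1.59 ± 0.41 and the blue copper protein gene BCB at -1.31 ± 0.16. AT1G50040 was at -1.50 ± 0.06, MOM1 itself at -1.45 ± 0.01 and CYCB1;5 at -1.39 ± 0.30. The authors' deposited tables called these 8 down in both, but by limma 0 genes fell, while 682 had a negative ratio and 567 a positive ratio at an unadjusted p under 0.05. The lowest adjusted limma p of the 8 was 0.0858, for MOM1 and AT1G50040.

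Of the gene lists, the transposon class had the lowest adjusted p in mom1 by camera at the preset correlation. Its 189 measured members had a median log2 ratio of 0.16 and a mean of 0.83 (adjusted p = 1.6e-21). Of these members 74 reached 1 FPKM in mom1 alone and 7 in WT alone, so what was measured depends on the change itself. The 115 members that reached 1 FPKM in WT, a minimum chosen after the data were seen, had a median of 0.00 and a mean of 0.14. With no filter, over 1584 members, the median was 0.00955 and the mean 0.14 (adjusted p = 0.000957). By limma 12 of them rose over all genes, and when adjusted over the list alone 69 rose and 7 fell. With an estimated correlation its adjusted p was 0.675, and the same adjusted p of 0.675 or more was found for every list. The fit has 1 residual degree of freedom. The 1536 other pericentromeric genes did not pass camera (median 0.01, adjusted p = 0.225), although 5 of them rose over all genes and 19 when adjusted over the list alone. Of the known silenced loci, 3 of 12 were measured and 3 rose when adjusted over the list alone, against 1 (SDC) over all genes. Their median was 2.70 (camera adjusted p = 1.78e-08, and 0.675 with an estimated correlation), but 2 of the 3 reached 1 FPKM in mom1 alone. With no filter, over 10 members, the median was 0.00452 (adjusted p = 0.0109, and 0.793 with an estimated correlation). The other members were APUM9, a pumilio gene, at 2.70 ± 0.60 and QQS, a starch regulator, at 1.96 ± 0.26.

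Lists that passed camera in mom1 but followed 1 of the 2 tables came next. The morning clock genes passed upward (adjusted p = 0.00191, and 0.675 with an estimated correlation), with a median of 0.55 in replicate 1 and -0.05 in replicate 2. CDF1, PRR9 and LNK1 were called up in the authors' deposited table of replicate 1, at 1.03, 0.80 and 0.65. CDF1 and PRR9 made up the 2 members that rose when adjusted over the list alone, against 0 over all genes, and CCA1 was at 0.24 ± 0.44. The day and evening clock genes passed downward (adjusted p = 0.0127, and 0.675 with an estimated correlation), with medians of -0.41 and -0.04. They did not pass with a pseudocount of 0.1 (0.0511), and neither clock list passed without the replicate block (0.151 for morning, 0.326 for day and evening). FKF1 and PRR5, both near 0 FPKM in the second set of libraries, were at -0.56 and -0.64 in replicate 1, while ELF4 was at -0.30 ± 0.15 and BOA at -0.23 ± 0.26. Both clock lists also differed between the 2 sets of libraries, as did heat response, with a median of 1.12 for WT replicate 2 minus WT replicate 1 and 12 of 14 genes above 0, and the seed markers. Seed markers passed downward (adjusted p = 0.0127, and 0.675 with an estimated correlation) with a median of 0.10 in replicate 1 and -1.67 in replicate 2. Of the 7 measured, 4 reached 1 FPKM in WT alone, and with no filter the mom1 median over 13 was -0.45 (adjusted p = 0.0271), beside -0.71 over the 7. All 13 seed markers were higher in WT replicate 2 than in WT replicate 1, at a median of 2.63 against 0.00998 FPKM. The storage protein genes CRU3, SESA2 and SESA3 and the oleosin gene OLEO1 were at -1.74, -2.40, -2.19 and -1.54 in replicate 2.

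Root markers passed camera downward (adjusted p = 0.0127, and 0.675 with an estimated correlation) with medians of -0.08 and -0.39. The 3 genes of thalianol synthesis, THAS, THAH and THAD, were at -1.66, -1.64 and -1.96 in replicate 2 and at 0.07, 0.28 and 0.03 in replicate 1, and the cell wall gene PRP3 was at -0.46 ± 0.33. Jasmonate and wounding genes passed upward (adjusted p = 0.0461, and 0.675 with an estimated correlation) with medians of 0.49 and -0.19. They did not pass with a pseudocount of 0.1 (0.0516) or without the replicate block (0.0546). JAZ5, OPR3 and JAZ7 were at 0.75 ± 0.30, 0.49 ± 0.38 and 0.42 ± 0.14, and the defensin gene PDF1.2 was at -0.90 ± 0.70. Nuclear photosynthesis genes passed upward (adjusted p = 0.0361, and 0.675 with an estimated correlation) with medians of 0.04 and 0.16. They too did not pass with a pseudocount of 0.1 (0.0516) or without the replicate block (0.144). LHCB3, LHCA1, LHCB6 and LHCB1.2 each stood between 0.15 and 0.18. Flowering-time genes passed downward (adjusted p = 0.0487, and 0.675 with an estimated correlation) with medians of -0.07 and -0.25. They did not pass with a pseudocount of 0.1 (adjusted p = 0.0516, median -0.23) or with centred ratios (0.0520, median -0.16). In both the p, close to the threshold, crossed it. FLC, the floral repressor, fell by 0.82 on the log2 scale when adjusted over the list alone (SD 0.08), though not over all genes. MAF4, MAF5 and TFL1 were at -0.60 ± 0.55, -0.52 ± 0.61 and -0.26 ± 0.25.

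The remaining lists did not pass camera in mom1. Abscisic acid, cold and drought genes had a median of -0.03, a mean of 0.23 and an upward test (adjusted p = 0.225), so median and test differ in sign. RD29B at 1.45 ± 0.41 and CBF3 at 0.65 rose when adjusted over the list alone, and 0 rose over all genes. CBF2, NCED3 and CBF1 were at 0.84 ± 0.54, 0.81 ± 0.94 and 0.67 ± 0.55. Salicylic acid defence had an adjusted p of 0.225 and a median of 0.07, but passed upward with no filter (adjusted p = 0.0274, median 0.12 over 16 members, and 0.793 with an estimated correlation). Its members included PR1 at 3.28 and 0.77 in the 2 tables, PR2 at 0.66 and -2.01, and WRKY70 and SARD1 at means of -0.64 and 0.29. Heat response had an adjusted p of 0.336 and a median of 0.08. Its HSP17.6A was at 0.51 ± 0.10, HSP17.4 at -0.17 ± 0.82, HSP101 at 0.16 ± 0.67 and HSP17.6C at 0.14 ± 0.02. RNA-directed DNA methylation had a median of -0.00221 (adjusted p = 0.572), with RDR2 at -0.30 ± 0.13, SUVH9 at 0.29 ± 0.25 and CLSY1 at -0.27 ± 0.13. Its AGO9 was at -0.61 ± 0.48 (called down in the authors' deposited table of replicate 1, at 0.151 FPKM against 1.22). The authors' deposited tables also called AGO9 down in the library labelled pial1/2 and in nrpe1, which share that WT library. It was not tested in the tables of WT replicate 2. Heterochromatin maintenance had a median of 0.02 (adjusted p = 0.400), with MORC6, VIM1, CMT3 and SUVH4 between 0.11 and 0.21. DNA demethylation had a median of 0.03, a mean of -0.01 and a downward test (adjusted p = 0.894). In it DME, ROS1 and DML2 were at -0.20, -0.15 and -0.15, and APE1L was at 0.15. The SUMO pathway had a median of -0.00499, a mean of -0.00458 and an upward test (adjusted p = 0.972), with SUM3 at -0.22, SUM5 at 0.14, OTS2 at 0.06 and HPY2 at -0.06. Of the flower markers 1 was measured, SEP3, at -0.23 ± 0.06 (adjusted p = 0.170). For the lists in this paragraph other than abscisic acid, 0 genes passed limma when adjusted over the list alone.

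The mom1 count rests on the pairing of the libraries. Without the replicate block limma called 0 genes, with 127 higher and 38 lower at an unadjusted p under 0.05. Leaving out any of the 4 libraries, which requires a fit without the block, also left 0 by limma (105 to 153 higher and 18 to 99 lower at an unadjusted p under 0.05), as did using no filter on low values (802 and 872).

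The loci with the highest ratios in mom1 were also high in the library labelled pial1/2. AT2G11778 was at 377 FPKM against 1.86 in WT, AT3G29639 at 179 against 1.54, AT4G04293 at 275 against 3.05, and AT2G15810 at 63.0 against 0.471. SDC stood at 67.6 FPKM against 0.553, a log2 ratio of 5.46 beside 5.37 in mom1 replicate 1. The named genes were completed by AT2G15800 at 5.62, AT3G44006 (chromosome 3, 15796238 to 15796417), listed at 0 in WT and at 38.4 FPKM in the mutant, and AT2G04460 at 5.16. ERF9 (AT5G44210, chromosome 5, 17806472 to 17807534), an ethylene-response transcription factor gene, was at 0.230 FPKM against 4.47. CYCB1;5 was at -1.58 in this library, HEI10, a meiotic crossover gene, at -1.45, and AT5G60610 at -1.07.

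The authors' deposited table called 153 genes up and 107 down in the library labelled pial1/2. Of the genes up in the authors' deposited table, 50 (32.7%) were of the transposon class, against 1.02% of the genes tested. Another 37 were other genes in the windows and 66 were other genes on the arms. The transposon class had a median log2 ratio of 0.12 over 136 measured members, at percentile 100 of matched random lists. The known silenced loci had a median of 3.56 at percentile 100, and other pericentromeric genes 0.00 at percentile 91.3. Loci silent in WT were measured only where they were high in the mutant, and with no filter the medians were 0.0220 for the transposon class (996 members) and 0.47 for the known silenced loci (6). Among the other lists, abscisic acid genes stood at percentile 99.99 (median 0.14), the SUMO pathway at 87.0 (0.04), day and evening clock genes at 89.4 (0.05), DNA demethylation at 70.1 (0.03) and salicylic acid defence at 65.6 (0.02). Flowering time was at percentile 47.4 (median -0.00379) and flower markers at 38.7 (-0.05). Lower percentiles were those of jasmonate and wounding at 0.0400 (-0.15), root markers at 0.0750 (-0.19), heat response at 1.01 (-0.19), photosynthesis at 3.18 (-0.08), morning clock genes at 4.82 (-0.12), RNA-directed DNA methylation at 19.5 (-0.03) and heterochromatin maintenance at 26.0 (-0.03). No seed marker was measured in this table.

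In pial2 the 110 genes up in both of the authors' deposited mom1 tables had a median log2 ratio of 0.01, and a smaller group was high. AT5G35480 was at 388 FPKM against 46.7 in WT, and its neighbour MRU1 at 60.5 against 8.65, log2 ratios of 3.03 and 2.67. AT4G04293 was at 3.22, SDC at 2.79, AT3G29639 at 2.03 and AT5G52070 (chromosome 5, 21161311 to 21165025) at 2.09. WRKY40, a stress-response transcription factor gene, was at 22.8 FPKM against 4.36, and CBF2, a cold-response regulator, at 11.9 against 2.05. ERF9 was at 0.122 FPKM against 4.07. Among the named lower genes were the chloroplast transcript ATCG00090 (-3.72), which is listed at 0 in the tables of WT replicate 1, and the seed storage genes CRA1, SESA2 and SESA3 (-2.25, -2.24 and -2.21).

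The authors' deposited table called 182 genes up and 345 down in pial2. Of the genes up in the authors' deposited table, 10 (5.49%) were of the transposon class, against 0.779% of the genes tested. Another 25 were other genes in the windows and 147 were other genes on the arms. The transposon class had a median of 0.04 over 109 members, at percentile 88.7, and other pericentromeric genes 0.02 at percentile 99.5. The known silenced loci, of which 2 were measured, had a median of 1.64 at percentile 99.6. With no filter their median was -0.0114 (9 members), the other direction, and that of the transposon class 0.000560 (933 members). Seed markers (median -2.01), root markers (-0.47), abscisic acid genes (-0.42) and jasmonate and wounding genes (-0.26) stood at percentile 0. With no filter the seed markers had a median of -0.90 (13 members). Photosynthesis was at percentile 0.190 (-0.11), flower markers at 2.72 (-0.71), the SUMO pathway at 9.42 (-0.09), heterochromatin maintenance at 9.97 (-0.09), morning clock genes at 10.9 (-0.09), flowering time at 17.1 (-0.09) and day and evening clock genes at 24.6 (-0.07). DNA demethylation was at 32.6 (-0.04), heat response at 35.2 (-0.03), RNA-directed DNA methylation at 41.3 (-0.02) and salicylic acid defence at 76.9 (0.05). As in the mom1 replicate 2 table, seed transcripts were lower in the mutant than in the WT library of this table. In both, the authors' deposited tables called the thalianol genes THAS, THAH and THAD down. Whether thalianol genes differ between the WT libraries was not tested.

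In mom1pial2 the 110 genes up in both of the authors' deposited mom1 tables had a median log2 ratio of 1.64, beside 1.48 in mom1 replicate 2. AT2G11778 was at 2238 FPKM against 16.8 in WT, AT3G29639 at 322 against 2.14, AT2G11780 at 98.1 against 0.235 and SDC at 47.0 against 0.357. AT4G04293 was at 6.43, AT3G42353 at 5.74, AT2G15800 at 5.53, AT2G15810 at 5.48 and AT1G36675 (chromosome 1, 13867568 to 13869490) at 5.17. The lowest were the beta-amylase gene BAM5 at -2.86, the phosphate-starvation genes PEPC1 and SPX3 at -2.15 each, and the floral repressor MAF5 at -1.97. The authors' deposited files called each of these down in all 3 tables of WT replicate 2 and in none of WT replicate 1. Over all genes, 71 were called down in all 3 tables of WT replicate 2, against 15 for WT replicate 1. A high level in that WT library and a fall in its mutants cannot be told apart here.

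The authors' deposited table called 178 genes up and 250 down in mom1pial2. Of the genes up in the authors' deposited table, 75 (42.1%) were of the transposon class, against 1.14% of the genes tested. Another 28 were other genes in the windows and 75 were other genes on the arms. The transposon class had a median of 0.19 over 160 members, at percentile 100, known silenced loci 2.83 at percentile 99.995, and other pericentromeric genes 0.03 at percentile 99.96. With no filter the known silenced loci were at -0.0106 (9 members), the other direction, and the transposon class at 0.0139 (1118 members), since members silent in WT were measured only through the mutant. Seed markers stood at percentile 0 (-0.77, and -0.42 over 13 members with no filter). Jasmonate and wounding was at 0.0300 (-0.24), flowering time at 0.1 (-0.35), heat response at 0.235 (-0.22), photosynthesis at 1.01 (-0.12), root markers at 6.72 (-0.10) and morning clock genes at 9.02 (-0.12). Abscisic acid genes were at 24.0 (-0.03), DNA demethylation at 25.4 (-0.05), flower markers at 39.2 (-0.04), RNA-directed DNA methylation at 39.7 (-0.01), heterochromatin maintenance at 45.3 (-0.01), the SUMO pathway at 48.5 (-0.00356), day and evening clock genes at 54.4 (0.01) and salicylic acid defence at 80.0 (0.07).

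The double mutant was then set against its single mutants, all tabulated with WT replicate 2. Over the 110 genes called up in both of the authors' deposited mom1 tables, the median difference of log2 ratios was 0.01 for mom1pial2 minus mom1 and 1.06 for mom1pial2 minus pial2. Over the 182 genes called up in the authors' deposited pial2 table, the medians were 0.15 and -0.28. Each of these sets was chosen by calls in a single mutant, which favours that mutant. Over the 222 genes called up in the authors' deposited table of mom1 replicate 1, a library outside these differences, the medians were 0.02 for mom1pial2 minus mom1 and 0.53 for mom1pial2 minus pial2. Over the 270 genes of either set they were 0.08 (quartiles -0.12 and 0.29) and -0.09 (quartiles -0.38 and 0.80). The genes furthest above the higher single mutant were AT2G17660 (by 1.3), the ethylene-response factor gene RRTF1 (1.13), THAD (0.97), THAH (0.92) and AT5G52020 (0.89). Of these, THAD and THAH lay below WT in all 3 mutants. The genes furthest below were ERF9 (-2.30), MYB77 (-1.54) and PHI-1 (-1.53). ERF9 was at 0.304 FPKM in mom1pial2 and 0.122 in pial2 and 5.33 in mom1 replicate 2. No test was run on these differences, since each genotype has 1 library in this set.

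**Figure D5:**
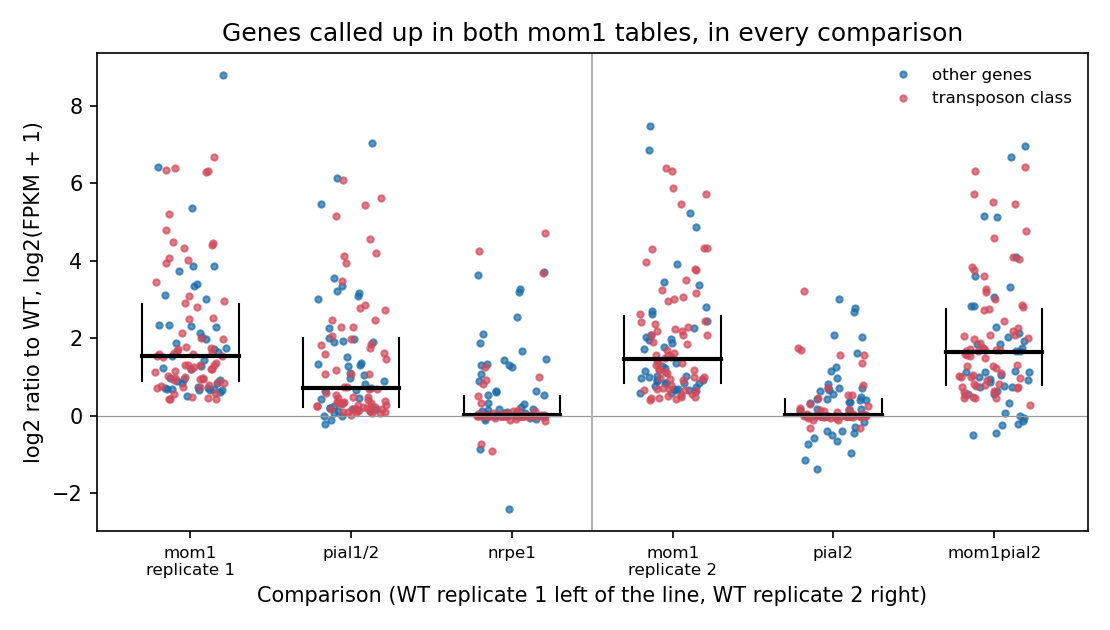
Log2 ratio to WT of the 110 genes called up in both of the authors' deposited mom1 tables, in each of the 6 comparisons, with horizontal bars at the median and vertical lines for the quartiles. The medians are 1.54 and 1.48 in mom1, 1.64 in mom1pial2, 0.72 in the library labelled pial1/2, 0.01 in pial2 and 0.02 in nrpe1.

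In nrpe1 the 110 genes up in both of the authors' deposited mom1 tables had a median log2 ratio of 0.02. The authors' deposited nrpe1 table tested 52 of them and called 23 up. Of the named genes high in nrpe1, AT5G27845 and AT4G04293 are among the 110. AT3G32240 (transposon class, chromosome 3, 13209736 to 13212216) was at 61.5 FPKM against 0.0366 in WT, and stood at 0.0244 in mom1 replicate 1. The neighbours AT1G33840 and AT1G33850 (chromosome 1, 12283862 to 12285306 and 12287913 to 12288210) were at 37.8 and 25.6 FPKM, the latter listed at 0 in WT. AT5G27845 was at 30.7 against 0.203, AT5G41830 at 14.6 against 0.0234 and AT4G04293 at 77.4 against 3.07. AT3G28899, listed at 0 in WT, was at 103 FPKM, and the transcribed RSU1 locus at 127 against 6.17. ROS1 (AT2G36490, chromosome 2, 15308021 to 15314807), the DNA glycosylase that removes methylcytosine, was at 1.84 FPKM against 16.1. HEI10 was at 2.37 against 19.3, QQS at 0.727 against 8.22, and AT4G16215 was listed at 0 against 2.97.

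The authors' deposited table called 264 genes up and 147 down in nrpe1. Of the genes up in the authors' deposited table, 30 (11.4%) were of the transposon class, against 0.944% of the genes tested. Another 38 were other genes in the windows and 196 were other genes on the arms. The transposon class had a median of 0.01 over 121 members, at percentile 35.4, and other pericentromeric genes 0.00 at percentile 91.5. The known silenced loci had a median of 1.35 at percentile 99.9, with SDC at 3.19, APUM9 at 1.35 and QQS at -2.42, and with no filter a median of 0.20 (5 members). Salicylic acid defence (0.41) and jasmonate and wounding (0.37) stood at percentile 100. The authors' deposited table called 5 of the salicylic acid genes up, PR1 at 3.89, PR2 at 0.82, WRKY70 at 0.75, PR5 at 0.71 and SARD1 at 0.70. PR1 was also called up in the authors' deposited tables of mom1 replicate 1 and the library labelled pial1/2, which share this WT library. It was called in none of the tables of WT replicate 2. Morning clock genes were at percentile 94.8 (0.12), flower markers at 92.2 (0.33), heterochromatin maintenance at 89.8 (0.06), abscisic acid genes at 85.7 (0.02), RNA-directed DNA methylation at 79.6 (0.04), DNA demethylation at 68.3 (0.04) and the SUMO pathway at 67.8 (0.01). Root markers were at 30.0 (-0.02), flowering time at 16.2 (-0.06), photosynthesis at 10.1 (-0.07), day and evening clock genes at 3.27 (-0.09) and heat response at 0.170 (-0.22). No seed marker was measured in this table.

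Over the 110 genes called up in both of the authors' deposited mom1 tables, nrpe1 minus mom1 had a median log2 difference of -1.11 (quartiles -2.27 and -0.66), and nrpe1 was the lower in 101. With a pseudocount of 0.1 this median difference was -3.01. These genes were chosen by their mom1 calls, so a lower nrpe1 value was built in. Over the 264 genes called up in the authors' deposited nrpe1 table, the medians were 0.72 in nrpe1 and 0.30 and 0 in the 2 mom1 tables. Both mutants had 23 genes called up in the authors' deposited tables, against 0.569 for independent lists, and 21 called down, against 0.368, but nrpe1 shares its WT library with mom1 replicate 1, which adds shared calls with no effect. The named shared genes were AT4G04293, AT3G29639, SDC, AT2G04460 and the non-coding RNA AT4G04223, at log2 ratios of 4.27, 3.63, 3.19, 3.68 and 3.27 in nrpe1. Of the AT4G04223 windows 66.4% occur elsewhere in the genome. A cluster on chromosome 5 went the other way. AT5G34790 (12966080 to 12968155) and AT5G34795 (12969406 to 12970836) were called up in the authors' deposited tables of both mom1 replicates and of the libraries labelled pial1/2, pial2 and mom1pial2, with log2 ratios between 1.61 and 2.25. In nrpe1 the authors' deposited table called them down, at -0.73 and -0.85. The adjoining AT5G34800, chosen after its values were seen, had the same calls in the authors' deposited tables, with -0.92 in nrpe1.

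Across mutants, the genes up in both of the authors' deposited mom1 tables included 96 also called up in mom1pial2, 63 in the library labelled pial1/2 and 22 in pial2. Independent lists would give 0.880, 0.579 and 0.419. The counts have unequal bases, since the authors tested 109 of these genes in mom1pial2, 84 in the library labelled pial1/2 and 50 in pial2. Each of these mutants shares a WT library with 1 of the mom1 tables, and the contrast of the library labelled pial1/2 with pial2 is confounded with the set of libraries. Together, mom1, the library labelled pial1/2 and mom1pial2 had 61 genes up in the authors' deposited tables, and with pial2 as well 19. Of these 19 genes, 10 were also up in the authors' deposited nrpe1 table, and 13 lie in the windows. The named members of this core were AT4G04293, AT3G29639, AT5G35480, MRU1, SDC, AT5G52070, AT2G04460, AT5G27845, AT5G34790 and AT5G34795. Their smallest log2 ratio among these mutants ranged down to 1.57, for AT5G27845 in pial2. Of the 53 genes down in both of the authors' deposited mom1 tables, 36 were also down in mom1pial2, 14 in pial2 and 8 in the library labelled pial1/2, against 0.614, 0.800 and 0.259 for independent lists.

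Pairs of tables that share a WT library also share its chance values. These were simulated for unchanged mutants over the 18886 genes expressed in all 6 tables, which leaves out loci silent in WT unless every mutant expressed them. Each simulated mutant was given as many genes up and down as the authors had called, taken by rank and with no test. The simulated overlaps therefore show what shared WT noise does to lists of that size. They are not the false calls that the authors' test would give for unchanged mutants. The simulated ratios had an SD of 0.158 with normal noise and between 0.253 and 0.255 with noise resampled from the differences of the 2 mom1 ratios, a version chosen after the data were seen, beside observed SDs between 0.235 and 0.347. Over these genes the authors' deposited tables of mom1 replicate 1 and the library labelled pial1/2 shared 32 up, against 0.414 for independent lists, 8.34 with normal noise and 33.5 with resampled noise. Their covariance of ratios across genes was 0.0345, against 0.0124 and 0.0327. For mom1 replicate 1 and nrpe1 the authors' deposited tables shared 36 up (0.926, 14.8 and 42.9), with a covariance of 0.0323 against 0.0125 and 0.0322. For mom1 replicate 2 and pial2 the authors' deposited tables shared 36 up (0.911, 14.6 and 46.6), with a covariance of 0.0650 against 0.0125 and 0.0321. With resampled noise none of these 3 pairs shared more genes up than the simulation gave. That noise was drawn across the 2 sets of libraries. Its SD exceeded the whole observed SD of the library labelled pial1/2 (0.241) and of nrpe1 (0.235). It therefore cannot show that these pairs behave as unchanged mutants. For mom1 replicate 2 and mom1pial2 the authors' deposited tables shared 50 up (0.513, 9.85 and 36.4), with a covariance of 0.0847 against 0.0125 and 0.0323. Of genes down, the authors' deposited tables of these 4 pairs, in the same order, shared 17 (17.005 with normal and 44.9 with resampled noise), 56 (22.65 and 59.7), 98 (41.6 and 93.7) and 132 (35.0 and 85.6). Part of any excess may come from the shared WT library, which cannot be split. With different WT libraries, over all genes tested, the authors' deposited tables shared 105 genes up for mom1 replicate 1 and mom1pial2 (1.51 independent). They shared 64 for mom1 replicate 2 and the library labelled pial1/2 (1.21). For mom1 replicate 2 and nrpe1 they shared 30 (1.56), and for mom1 replicate 1 and pial2 24 (0.988). Over the 18886 genes these pairs shared 28, 24, 21 and 18, in the same order. Their covariances over those genes were 0.0241, 0.0216, 0.00858 and 0.0101.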

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

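Of the tests in this part, summing entries that share a locus, a minimum of 1 FPKM in WT and resampled noise were chosen only after the data were seen. Summing gave 18 genes by limma, 16 of them among the reported 18. Centring the ratios gave the same 18, and a pseudocount of 0.1 gave 21, of which 14 were among the 18. The fit of all 8 libraries equals the reported fit by construction and says nothing about stability. Limma gave 0 mom1 genes without the replicate block, 0 with no filter on low values (more genes tested), 0 on leaving out each library (unblocked fits in which a lone library is assumed to vary like the other group), 30 at 5 FPKM and 32 with a trend. The deviations of same-numbered WT and mom1 libraries correlated at 0.835 across 20517 genes, with 2 pairs. Genes called in both of the authors' deposited mom1 tables numbered 65 up and 10 down with a 2-fold minimum, and 31 down at a q-value below 0.01. Apart from the authors' calls, 10 genes were down when all mom1 levels had to lie 2-fold beyond all WT levels. That count has no replicate block and compares levels across separately normalized tables. A single mom1 table in the authors' deposited files gave 212 to 222 up and 249 to 295 down. With a 2-fold minimum the authors' deposited tables gave 64 up and 6 down in the library labelled pial1/2, 50 and 76 in pial2, 104 and 82 in mom1pial2, and 87 and 20 in nrpe1. At a q-value below 0.01 the authors' deposited tables gave 105 up and 213 down in pial2, 175 and 94 in nrpe1, 161 down in mom1pial2 and 57 down in the library labelled pial1/2.

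Of 9 lists passing camera, 4 passed with a pseudocount of 0.1, 5 without the replicate block, 0 with an estimated correlation and 0 with fry. Those lost with a pseudocount of 0.1 were jasmonate and wounding, photosynthesis, seed markers, flowering time, and day and evening clock genes (adjusted p between 0.0511 and 0.0516). Those lost without the replicate block were jasmonate and wounding, photosynthesis and both clock lists (adjusted p between 0.0546 and 0.326). Salicylic acid defence passed only with no filter (adjusted p = 0.0274), and flowering-time genes no longer passed with centred ratios (0.0520). For the transposon class in mom1 the adjusted p was 0.675 with an estimated correlation and 0.181 with fry. Its median was 0.19 with a pseudocount of 0.1, 0.00955 with no filter, which adds genes near 0, 0.00295 with a minimum of 1 FPKM in WT, which removes loci silent in WT, and 0.15 to 0.19 leaving out each replicate. In the library labelled pial1/2 it was 0.16 with a pseudocount of 0.1 and 0.0220 with no filter, and in mom1pial2 0.0139 with no filter. Among lists passing camera, medians that reversed when a replicate was left out were those of jasmonate and wounding (-0.19 to 0.49), morning clock genes (-0.0510 to 0.55) and seed markers (-1.67 to 0.10). Among the others they were heat response (-0.27 to 0.41), abscisic acid (0.07 to 0.12 against -0.03) and DNA demethylation (-0.02 to 0.06). With no filter the known silenced loci were at 0.00452 in mom1, -0.0114 in pial2 and -0.0106 in mom1pial2. Genes up in mom1 and pial2 numbered 24 to 45 in the authors' deposited tables leaving out each replicate, and in mom1 and nrpe1 30 to 53. The median of nrpe1 minus mom1 was -3.01 with a pseudocount of 0.1. The cause was not tested except where stated. Of the other values with alternatives, leaving out fits that called nothing or equal the reported fit, 882 stayed as reported, 13 lost and 19 gained a call, 56 moved beyond their spread and 5 reversed. With 2 libraries per group at most and no counts, a difference that was not called is not shown to be absent.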

Other observations

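Of the tests in this part, those of scaling, of MOM1 loss, of chance and of the WT stock were chosen only after the result was seen. Of genes chosen after their values were seen, the phosphatase genes HAI2, HAI1 and ABI1 had mean log2 ratios in mom1 of 1.07 ± 0.20, 0.77 ± 0.11 and 0.77 ± 0.12 (SD, n = 2 tables), and the transcription factor genes HB-12 and HB-7 of 0.80 ± 0.06 and 0.65 ± 0.02. The authors' deposited tables called these 5 up in both mom1 tables, and none of them passed limma. In pial2, HAI1, HAI2 and ABI1 were at -1.14, -0.73 and -0.39, and the authors' deposited table called HAI1 and HAI2 down. In mom1pial2 HAI2, HAI1, ABI1, HB-12 and HB-7 were at -0.13, -0.50, -0.22, 0.07 and -0.05, and the authors' deposited table called none of them there. RAB18, of the fixed abscisic acid list, was at -0.08 and -0.71 in mom1 and was called down in the authors' deposited table of replicate 2. The superoxide dismutase gene CSD1, also chosen after its values were seen, was at -0.85 and -1.78 in the 2 mom1 tables, -1.86 in pial2, -1.39 in mom1pial2 and -0.55 in nrpe1, but 0.09 in the library labelled pial1/2, and CSD2 was at -2.04 in pial2, -1.26 in nrpe1 and -0.08 in the library labelled pial1/2.

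ERF9 was low in the 3 libraries whose labels name pial2, at 0.230, 0.122 and 0.304 FPKM, and stood at 4.67 and 5.33 in mom1 and 4.2 in nrpe1. It lies on the same chromosome as PIAL2, and no cause of its low level was tested. The floral repressor FLC was at 0.671 FPKM in mom1pial2 against 4.07 in WT, with MAF4 at 0.744 against 4.41 and MAF5 at 0.687 against 5.6. In pial2 MAF5 was at -1.42 and FLC at -0.57. AT4G22390, chosen after its values were seen, lay between -0.97 and -0.71 in all 6 comparisons. Among 279 organellar entries, 113 were tested by the authors in pial2 and 0 in the tables of WT replicate 1. The authors' deposited tables called 17 of them down in pial2 and 2 each in mom1 replicate 2 and mom1pial2. The median log2 ratio over the tested entries was -0.35 in pial2, -0.19 in mom1 replicate 2 and -0.24 in mom1pial2. The small nucleolar RNA AT2G05765 was listed at 0 in WT replicate 2 and at 3450.4 FPKM in mom1 replicate 2, and was not called. QQS was high in mom1 (39.9 FPKM against 8.22 in replicate 1) and low in nrpe1 (0.727).

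Clock genes set the libraries of WT replicate 1 apart from those of WT replicate 2. Scaling of separately normalized tables would move morning and evening genes the same way, but their median differences lay 4.83 apart on the log2 scale, with opposite signs. A different time of day at harvest, tested on clock genes left off the fixed lists, predicts dawn genes up and dusk genes down in WT replicate 2. Their medians were 2.59 (6 of 7 above 0, RVE7 being the exception at -0.77) and -3.11 (0 of 4), a difference of 5.70. A different time of day at harvest may therefore explain this pattern, as a hypothesis, since the labels give no harvest time and other differences between the sets, such as growth or sequencing batch, stay untested.

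Seed transcripts were lower in the mutants tabulated with WT replicate 2. In pial2 the MOM1 transcript was not lost, at 4.13 FPKM against 4.98 in WT, and MOM1 protein was not measured. There the 7 measured seed genes, all below 0, had a median log2 ratio of -2.01, which restates the pattern and does not test MOM1 function. The minimum of 1 FPKM admits genes high in WT alone, and over all 13 fixed seed genes the pial2 median was -0.90. For mom1 replicate 2 and mom1pial2 loss of MOM1 as a cause stays open (-1.67 and -0.77 over the 7 measured, -0.85 and -0.42 over all 13). In the other mom1 table the 13 fixed seed genes (median log2 ratio 0.0142) stood at a median of 0.00998 FPKM in WT, with no room to fall. Seed material in the WT replicate 2 library remains a possible explanation: of 7 seed genes left off the fixed list, 4 were higher in that library than in each of its 3 mutants. OLEO2 was at 3.06 FPKM against 0.258 in mom1 replicate 2, while SESA5 (0.208 against 0.955 in mom1pial2) and M17 (1.06 against 1.16 in mom1pial2) were lower in WT and HSD1 was listed at 0, a count between the bounds set for and against, so seed material and another difference of that library cannot be told apart.

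The authors' deposited files called 15 genes the same way in all 6 comparisons, of which 10 were up and 5 down, against 0.0871 for chance values of the WT libraries. The genes up were APUM9, AT2G04460, SDC, ESM1, AT3G29639, AT4G04293, AT5G27845, AT5G35480, MRU1 and AT5G52070, and those down were AT1G36185, AT1G62510, AT4G08100, AT4G08115 and SGS3. Reads shared between near-identical copies were argued against by a median of 0% of their 50-base windows occurring elsewhere, but stay open for AT3G29639 (14.2%) and, among the genes down, AT4G08115 (17.2%) and AT4G08100 (25.7%). A WT stock that differs from every mutant stock would give the same ratio in all 6 tables, whereas the genes up spread by a median of 2.82 on the log2 scale. The genes down spread by 0.36, so such a stock difference may account for these 5 genes, SGS3 (a gene of small RNA production) among them, and a shared effect of the mutations on them stays open.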
